A study of Mus musculus with 4 samples.

How the data were processed

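RNA of sorted CD4+CD8+ double-positive thymocytes was extracted, labelled with biotin by a 3' in vitro transcription kit and hybridised to Affymetrix arrays, per the labels' protocols, with 1 array per sample and 1 colour. RMA and Affymetrix Expression Console 1.1 are named in the submitters' processing notes. The deposited values were taken as log2 RMA signals per probe set: they lay between 2.19 and 13.5 on all 4 arrays with nearly equal quartiles, which is the scale of RMA output after quantile normalization, and they were not centred per gene. RMA compresses differences at the bottom and the top of its range. No scanner files or detection calls were used here, so background and saturation could not be judged per probe set. The values were used without further normalization.

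Probe sets were named from a table of the array platform's annotation. Of 45037 probe sets, 28898 had exactly 1 gene name, 551 had several and 15588 were not listed. The Entrez gene IDs of 28689 probe sets matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating. The 28898 probe sets named 17097 genes, of which 7180 had more than 1 probe set. Each gene was represented by its probe set with the highest mean over all 4 arrays. Of the 190 called genes, 105 had more than 1 probe set, and 0 of these had another probe set called in the opposite direction. A 3' probe set reads only part of a transcript, and probe sets of gene families such as the MHC class I, Gimap, Ly6 and haemoglobin genes can cross-hybridise.

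Samples were grouped by their titles, 2 arrays per label, and the labels share replicate numbers 1 and 2 without saying that a number marks a shared animal, day or batch. The arrays labelled as knockout and as wild type were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, no filter on dim probe sets and no covariate. This left 2 residual degrees of freedom per gene before moderation, to which the prior added 5.00. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 over all 17097 genes, two-sided, and the count at a log2 difference of at least 1 was also taken. A fold is 2 to the power of the log2 difference. The test was checked on simulated data with 200 changed genes among 17097 and variances drawn from the fitted prior, in 20 simulations of the comparison of the 2 labels. It recovered 42.1% of genes raised by 1 on the log2 scale, 46.8% of genes lowered by 1, 92.9% raised by 2, 92.3% lowered by 2 and 99.5% raised by 4, and 4.24% of its calls were false. Unchanged genes alone gave 0.15 calls per simulation. Genes were simulated as independent and with the variances that the test assumes. These shares therefore check the procedure and do not measure the false share on the real arrays.

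A set of 19 gene lists was fixed before the data were examined: FOXO1-linked genes, single-positive maturation and egress, effector cytokines and cytotoxicity, effector and lineage transcription factors, double-positive stage identity, double-negative and progenitor genes, T cell receptor signalling components, T cell receptor induced genes, published Gfi1 targets, cell cycle, apoptosis, interferon response, immediate-early and handling stress, glycolysis, and markers of B cells, myeloid and dendritic cells, gamma-delta T, NK and innate lymphoid cells, thymic epithelium and stroma, and erythroid cells and platelets. Of 420 genes on the lists, 372 had a named probe set and the others are not analysed here. The lists overlap: 9 of 16 measured FOXO1-linked genes, 11 of 19 published Gfi1 targets, 6 of 17 gamma-delta and innate lymphoid markers and 3 of 26 myeloid markers were also on another list, and Klf2, S1pr1, Il18r1, Maf, Id2 and Irf4 each counted in more than 1 list. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 19 lists. With the correlation estimated from the 4 arrays, none of the 19 lists was called. In 20 simulations a list of 25 genes shifted by 0.5 was called in 100% of runs, and 0.278% of unshifted lists were called, with independent genes.

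The rule for named genes was also fixed before the data were examined. It took Gfi1 and Foxo1, the 10 called genes with the largest increase and the 10 with the largest decrease whose groups do not overlap and whose symbol is not a clone name, and per list up to 4 called members with the largest change, or up to 2 members where none was called. List members outside this rule are named where they show what a list held. Alternatives were a replicate block, median centring, a second quantile normalization, filters on the dimmest 30% and 50% of probe sets, a prior without trend, a robust prior, the mean of all probe sets of a gene, an ordinary t statistic, other list tests, and leaving out each array. A fit with the mean of the cell cycle list as a covariate was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.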

Results

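The data were whole-transcriptome microarray profiles of CD4+CD8+ double-positive thymocytes, the immature T cells of the thymus that carry both coreceptors. The cells were sorted by flow cytometry from C57BL/6 mice. Of the 4 arrays, 2 were labelled as wild type and 2 as coming from mice in which the hCD2-iCre recombinase was combined with a floxed Gfi1 gene. Gfi1 is a zinc-finger transcriptional repressor of blood and lymphoid cells. Each array held values for 45037 probe sets, and 17097 genes could be named from 28898 of them. The medians of the 4 arrays lay between 3.53 and 3.55 on the log2 scale, and the lower quartiles between 2.97 and 3.02. The labels do not describe the wild-type mice as carrying the recombinase, so its own effect was not separable from that of the floxed gene. They did not state whether replicates came from separate animals, so p-values measure only the spread between these samples, and the number of arrays (2 per label) limits the precision. The question put to the data, from the series' own design, was how the transcriptome of double-positive thymocytes differed between the genotypes.

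The targeted gene was examined first. Gfi1 had 1 named probe set, and its signal was higher, not lower, on the arrays labelled as knockout: 11.39 ± 0.11 (SD, n = 2) against 10.13 ± 0.06 (SD, n = 2) on the arrays labelled as wild type, a difference of 1.27 ± 0.14 (SE) on the log2 scale (limma, adjusted p = 0.00781). Without wild-type replicate 2 the adjusted p was 0.0501, within a range of 0.000145 to 0.0501 over the alternatives fitted with limma's moderation. An ordinary t statistic called 0 genes, and so not Gfi1 (1219 at an unadjusted p under 0.05). The position of this probe set relative to the floxed part of the gene was not given in the sources used here. If it lies outside the deleted part, it checks nothing about the labels. Every direction below is therefore one between arrays labelled as knockout and arrays labelled as wild type. Foxo1, the forkhead factor that the series title names beside Gfi1, was represented by 1 named probe set, which gave 2.95 ± 0.06 and 3.08 ± 0.09 (SD, n = 2 each), near the lower quartile of all probe sets on every array. It was not called (adjusted p = 0.892), and at so low a signal a fall of Foxo1 was not detectable with this probe set. Probe sets without a single gene name may include others of Foxo1. The result therefore holds for the 1 named probe set and leaves open whether Foxo1 differed between the labels.

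The arrays labelled as knockout differed from those labelled as wild type mainly by higher signals. Il18r1, the ligand-binding chain of the interleukin-18 receptor, rose from 2.96 ± 0.16 to 10.56 ± 0.34 (SD, n = 2 each), a 194-fold difference in signal. Cd163l1, a scavenger receptor cysteine-rich family gene, rose 175-fold to 10.99 ± 0.01 (SD, n = 2). Pdlim4, which encodes a PDZ and LIM domain protein, rose 98.3-fold, Sertad4 77.5-fold, Chd7, a chromatin remodeller, 67.2-fold, and Atp8b4, a P4-type ATPase gene, 43.2-fold. Klf2, a transcription factor of quiescence and migration in mature T cells, rose 36.8-fold from 4.61 ± 0.12 to 9.82 ± 0.22 (SD, n = 2 each). Cers4, a ceramide synthase gene, rose 29.4-fold, Grhl3 27.5-fold and Rgmb, a bone morphogenetic protein co-receptor gene, 26.6-fold. These 10 genes had adjusted p between 0.000109 and 0.00332 (limma). They were the largest increases apart from 5830411N06Rik, a gene known by a clone name (430-fold). Several of them started near the lower quartile of all probe sets, and because the values came without detection calls, such a fold is a ratio of RMA signals and not of transcript amounts.

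Decreases were fewer and smaller. Sqor, the mitochondrial sulfide:quinone oxidoreductase, fell 14.0-fold, from 8.89 ± 0.06 to 5.08 ± 0.74 (SD, n = 2 each). P3h4 fell 9.12-fold and Cd44, the hyaluronan receptor, fell 8.93-fold, from 6.74 ± 0.10 to 3.58 ± 0.02 (SD, n = 2 each). Insl5, an insulin-like peptide gene, fell 6.70-fold. Fn3k (6.05-fold), Tdrd5 (5.57-fold), Papss2 (5.43-fold), Abcb9 (4.68-fold), Lonrf1 (4.55-fold) and Tmie (4.54-fold) completed the 10 largest decreases, with adjusted p between 0.00151 and 0.0266 over all 10 (limma). The calls of Fn3k, Tdrd5, Lonrf1 and Tmie were lost when either wild-type array was left out (adjusted p between 0.0502 and 0.129, limma), and that of Papss2 without wild-type replicate 2 (0.0807).

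Over all 17097 genes, limma with Benjamini-Hochberg adjustment called 190 at 0.05, of which 161 were higher and 29 lower on the arrays labelled as knockout. Of these, 178 differed at least 2-fold, 151 upward and 27 downward. The count changed when 1 array was left out: it fell without either wild-type array and rose without either knockout array. The number of lower genes moved in the same way. Such a fit takes the spread between arrays from the other label alone. The groups did not overlap for 5905 genes (34.5%), against the 33.3% that chance gives for 2 arrays against 2.

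**Figure D1:**
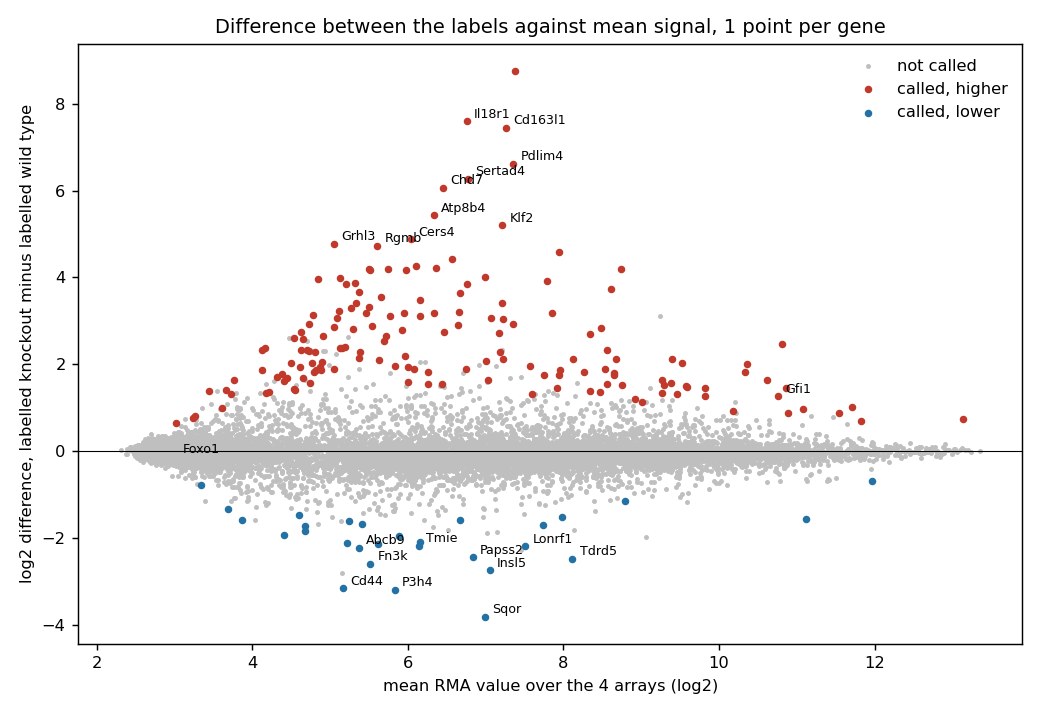
Each point is a gene, plotted by its mean RMA value over the 4 arrays (log2, x axis) and by the log2 difference of the arrays labelled as knockout minus those labelled as wild type (y axis); red and blue points are the 161 higher and 29 lower called genes, and the 10 largest named changes each way are labelled, with Gfi1 and Foxo1. The called genes lie mostly above 0, with Il18r1 and Cd163l1 near the top, and Gfi1 lies above 0.

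Of 26 measured genes of single-positive maturation and thymic egress, 8 rose on the arrays labelled as knockout, none fell and 18 did not pass the test. The list had a median log2 difference of 0.44 (camera, adjusted p = 2.63e-14; adjusted p = 0.239 with an estimated correlation), and 13 members rose when adjusted over the list alone. Besides Klf2, Gimap4, a GTPase gene of immune cells, rose 15.1-fold from 5.83 ± 0.40 to 9.75 ± 0.08 (SD, n = 2 each). Ly6c1, a surface antigen of mature and activated T cells, rose 14.5-fold, and Itgb7, the integrin beta 7 chain of gut homing, 7.56-fold. Cd53, a tetraspanin, rose 5.51-fold, H2-K1 4.08-fold and H2-D1 1.90-fold (both MHC class I heavy chains). S1pr1, the sphingosine-1-phosphate receptor required for thymic exit, rose 2.69-fold, from 3.83 ± 0.25 to 5.25 ± 0.06 (SD, n = 2 each). The rise was not shared by the whole list: Gimap5 and Gimap6 differed by -0.56 and -0.42 (adjusted p = 0.650 and 0.544, limma), Bcl2 by -0.36 (adjusted p = 0.940) and Cd52 by -0.03. The call of S1pr1 was lost without wild-type replicate 1 or 2 (adjusted p = 0.0966 and 0.246, limma).

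Of 16 measured genes linked to FOXO1 in T cells, 3 rose, none fell and 13 did not pass. These were Klf2, S1pr1 and Ctla4, the inhibitory receptor of activated and regulatory T cells, which rose 14.5-fold from 3.28 ± 0.41 to 7.13 ± 0.60 (SD, n = 2 each). Adjusted over the list alone, 4 rose, the further one being Ikzf2 with a difference of 0.89. The recombinase genes Rag1 and Rag2, also on this list, differed by -0.05 ± 0.09 and 0.08 ± 0.12 (SE). The list's median was 0.06 and its mean 0.71 (camera, adjusted p = 0.00589; adjusted p = 0.361 with an estimated correlation and 0.391 on ranks).

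Of 34 measured genes of effector cytokines, their receptors and cytotoxicity, 2 rose and 32 did not pass. They were Il18r1 and Gzma, which encodes granzyme A and rose 3.14-fold from 9.79 ± 0.16 to 11.44 ± 0.16 (SD, n = 2 each). The cytokine genes Ifng, Il4 and Il17a had group means below the medians of the arrays under both labels, at 2.78, 3.04 and 3.51 on the arrays labelled as knockout, with differences of -0.14, 0.10 and 0.06 (adjusted p of at least 0.893, limma). Adjusted over the list alone, 7 rose, among them Tnf, which encodes tumour necrosis factor, with a difference of 0.65 (adjusted p = 0.129 over all genes). Differences lay above 0 for 27 of the 34 members, with a median of 0.17 (camera, adjusted p = 8.13e-08 and 0.000275 on ranks; adjusted p = 0.373 with an estimated correlation). Among 23 measured effector and lineage transcription factors, 4 rose and none fell. Maf, a regulator of several helper and innate-like T cell programmes, rose 15.5-fold from 2.87 ± 0.06 to 6.83 ± 0.84 (SD, n = 2 each). Id2, an inhibitor of E proteins, rose 3.35-fold, Irf4, an activation-induced factor, 2.48-fold, and Stat4, the interleukin-12 signal transducer, 2.21-fold. Tbx21 and Zbtb16, the factors of type 1 and innate-like lineages, differed by 0.10 and 0.03 and were not called (adjusted p = 0.949 and 1.00). Adjusted over the list alone, 6 rose and 2 fell. The median was 0.15 (camera, adjusted p = 5.47e-05; adjusted p = 0.361 with an estimated correlation), and the calls of Id2, Irf4 and Stat4 were lost without wild-type replicate 2 (adjusted p = 0.167, 0.159 and 0.206, limma). Those of Irf4 and Stat4 were also lost without wild-type replicate 1 (adjusted p = 0.0581 and 0.202).

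Interferon response genes formed the list with the highest median. Of 24 measured members, 5 rose, none fell and 19 did not pass, and 17 rose when adjusted over the list alone. Ifi27l2a rose 13.3-fold from 6.75 ± 0.32 to 10.48 ± 0.12 (SD, n = 2 each). Rsad2, which encodes viperin, rose 7.51-fold, Ifit1 6.94-fold, Usp18, a negative regulator of interferon signalling, 6.59-fold, and Rtp4 6.51-fold. The call of Usp18 was lost without the intensity trend (limma, adjusted p = 0.0548). The median log2 difference was 1.06 (camera, adjusted p = 3.48e-19; adjusted p = 0.319 with an estimated correlation). Leaving out any array kept the camera call, with adjusted p of at most 5.08e-16.

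**Figure D2:**
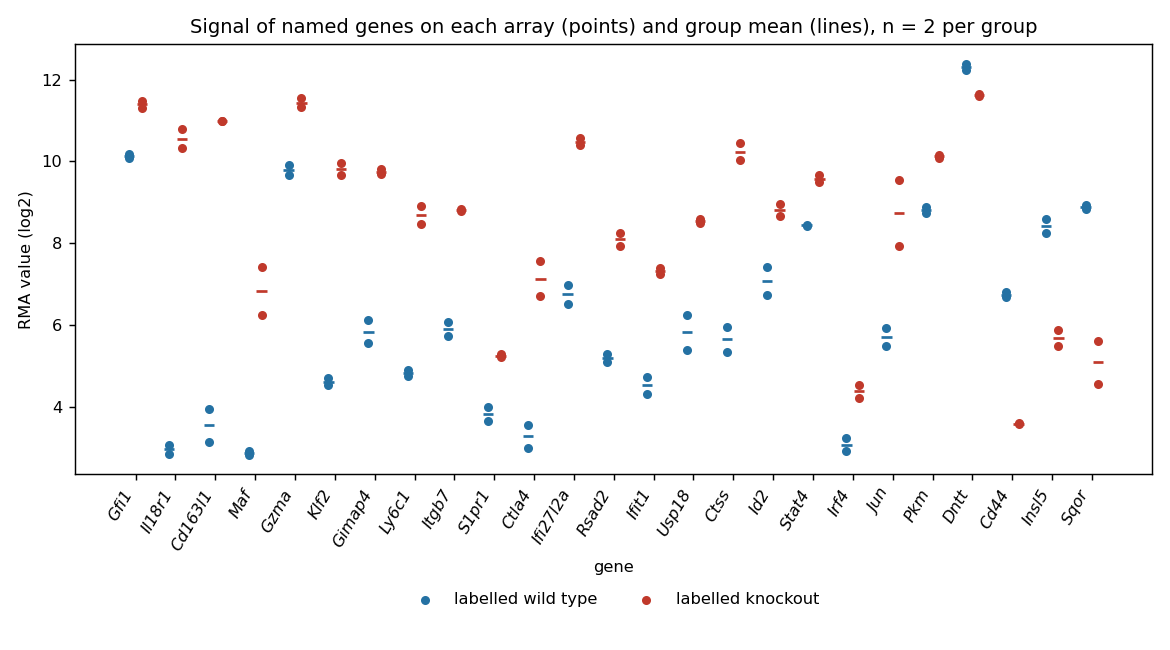
Each point is the RMA value (log2, y axis) of a gene on 1 array, in blue for the 2 arrays labelled as wild type and in red for the 2 labelled as knockout, with the group mean as a line. Il18r1, Cd163l1 and Maf lie between 2.83 and 3.94 on the arrays labelled as wild type, Gfi1 is higher on the arrays labelled as knockout, and Dntt, Cd44, Insl5 and Sqor are lower there.

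Genes of the double-positive stage list, some of which other T cells also express, differed little. Of 26 measured members, none rose, 1 fell and 25 did not pass. The one that fell was Dntt, which encodes terminal deoxynucleotidyl transferase and fell 1.61-fold from 12.31 ± 0.12 to 11.62 ± 0.03 (SD, n = 2 each). The coreceptor genes Cd4, Cd8a and Cd8b1 differed by -0.23, -0.04 and -0.17, each with an adjusted p of at least 0.861 (limma). The list's median was -0.05 and its shift was not called (camera, adjusted p = 0.119), and the call of Dntt was lost without wild-type replicate 1 or 2 (adjusted p = 0.123 and 0.266). The outcome for the list changed without wild-type replicate 1 or knockout replicate 1, in fits of 1 array against 2. Of 24 measured double-negative and progenitor genes only Cd44 was called, and the shift was not (median 0.07, mean -0.003, adjusted p = 0.471). Of 21 measured T cell receptor signalling components none was called (camera, adjusted p of the list = 0.241, an outcome that changed without knockout replicate 1). The largest differences there were -0.88 for Ptpn22, a phosphatase gene, and 0.44 for Prkcq, a kinase gene (limma, adjusted p = 0.116 and 0.360). Without knockout replicate 1, with 1 knockout array left, Ptpn22 differed by -0.99.

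Of 24 measured genes induced by T cell receptor signals, only Irf4 rose (camera, adjusted p = 0.0138; adjusted p = 0.421 with an estimated correlation; median 0.13), and the call of the list was lost without knockout replicate 1 or wild-type replicate 2 (adjusted p = 0.112 and 0.214). Of 19 measured published Gfi1 target genes, only Id2 rose and none fell, with a median of 0.07 and 17 of 19 differences above 0 (camera, adjusted p = 0.00589; adjusted p = 0.421 with an estimated correlation). Of 21 measured immediate-early and handling-stress genes, only Jun, an AP-1 subunit gene, rose. It rose 8.20-fold, from 5.70 ± 0.31 to 8.74 ± 1.14 (SD, n = 2 each), a call that was lost without wild-type replicate 1 or 2 (adjusted p = 0.159 and 0.0923; list median 0.11; camera, adjusted p = 0.00501; adjusted p = 0.379 with an estimated correlation). Without wild-type replicate 2 the calls of the published target list and the immediate-early list were lost as well (adjusted p = 0.110 each). Of 19 measured glycolysis genes, only Pkm, the pyruvate kinase gene, rose (2.49-fold, a call lost without wild-type replicate 1 or 2 with adjusted p = 0.0730 and 0.103), and the list was not shifted (adjusted p = 0.866). None of 19 measured apoptosis regulators was called (list adjusted p = 0.866). The largest differences were 1.54 for Pmaip1 and -1.30 for Bid, with adjusted p = 0.162 and 0.160. With 1 knockout array left, Pmaip1 differed by 1.97 without knockout replicate 1 and by 1.11 without knockout replicate 2. Bid differed by -1.66 without knockout replicate 2.

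Cell cycle genes separated the 2 arrays labelled as knockout from each other. The mean over 29 measured members was 7.93 on knockout replicate 1 and 9.57 on knockout replicate 2, with all 29 higher on the latter. It was 8.59 and 8.97 on wild-type replicates 1 and 2. None of the 29 was called between the labels by its brightest probe set, the largest differences being 2.31 for Ccnd2 and 0.79 for Ccne1 (adjusted p = 0.136 and 0.607, limma). Of the other Ccnd2 probe sets, 2 were called higher in a limma fit of all probe sets, with differences of 2.69 and 1.67 (adjusted p = 0.0428 and 0.0444). For the brightest Ccnd2 probe set the difference was 3.16 without knockout replicate 1 and 1.47 without knockout replicate 2, each with 1 knockout array left. By camera, the list was not shifted (adjusted p = 0.866). Without knockout replicate 1 the list was higher on the remaining array labelled as knockout, and without knockout replicate 2 it was lower. These fits set 1 knockout array against 2 wild-type arrays. The genes of this list also moved together, with an estimated correlation of 0.859, so no call is drawn from these fits.

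Of the markers of other cells that a sort could hold, most members of each list had group means below the medians of the arrays. Of 26 measured myeloid and dendritic markers only Ctss, the cathepsin S gene, was called. It rose 24.1-fold from 5.65 ± 0.44 to 10.24 ± 0.30 (SD, n = 2 each), while Lyz2 and Tyrobp differed by 0.51 and 0.05 (adjusted p = 0.718 and 1.00). The list was not shifted (camera, adjusted p = 0.0857), but this outcome changed without wild-type replicate 1 or knockout replicate 1, in fits of 1 array against 2. Of 17 measured markers of gamma-delta T, NK and innate lymphoid cells, Il18r1, Cd163l1 and Maf rose and 14 did not pass (median 0.05; camera, adjusted p = 0.000154; adjusted p = 0.319 with an estimated correlation). Adjusted over the list alone, 4 rose, and 10 of the 17 differences lay above 0. Among members not called, Blk and Gata3 differed by 1.24 and 0.56, and Sox13 and Il17re by -0.05 and -0.28. Sox13 lay below the array medians under both labels, where a fall was not detectable. No member was called among 13 B cell markers (camera, adjusted p = 0.866; Cd79b and Ms4a1 differed by -1.23 and 0.19). None was called among 18 thymic epithelial and stromal markers (0.119; Epcam and Cldn4 differed by 1.68 and 1.26) or 12 erythroid and platelet markers (0.793; Car2 and Hba-a1 differed by -1.87 and 0.83). The outcome for the thymic epithelial list changed without wild-type replicate 1 or knockout replicate 2, in fits of 1 array against 2. Without knockout replicate 1, Cd79b differed by -1.79 and Car2 by -2.40. Without knockout replicate 2, Car2 differed by -1.35, Epcam by 2.15 and Cldn4 by 1.54. These fits set 1 knockout array against 2 wild-type arrays, so no call is drawn from them. Hba-a1, a haemoglobin gene, was higher on replicate 2 under both labels, at 7.35 and 10.2 on wild-type replicates 1 and 2 and at 8.72 and 10.5 on knockout replicates 1 and 2.

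**Figure D3:**
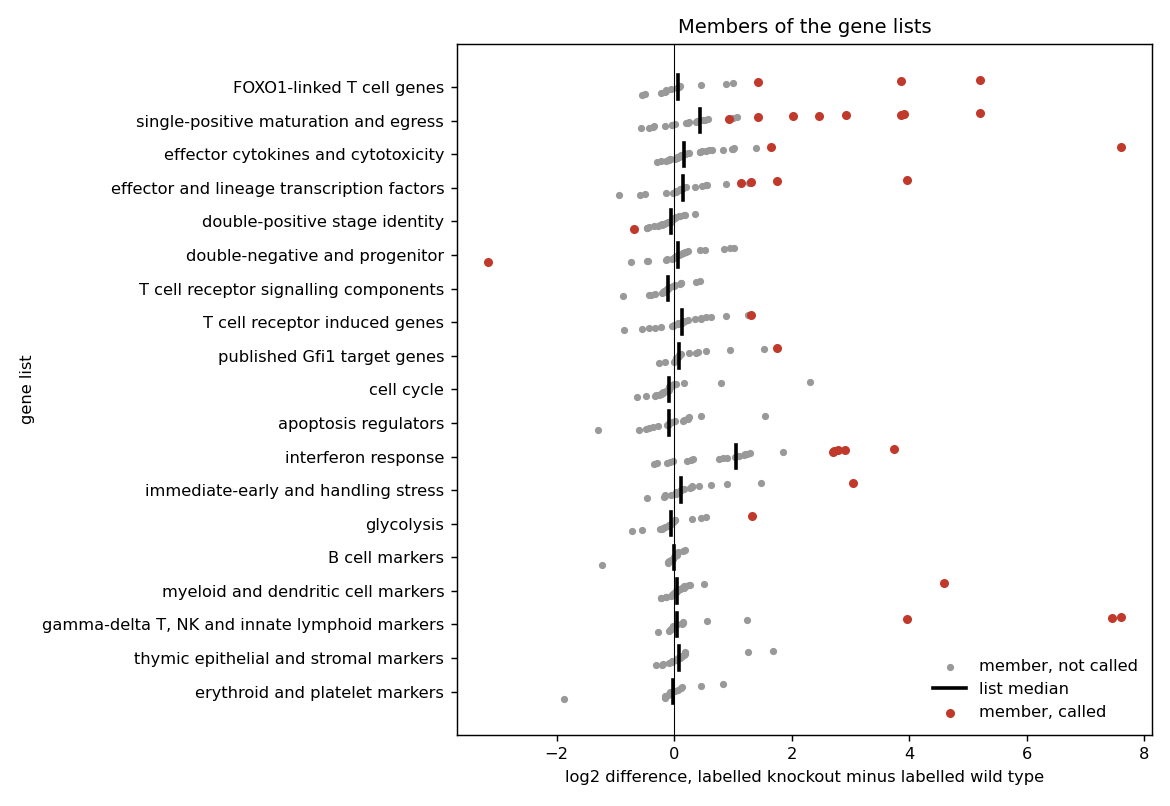
Each point is a measured member of a gene list, plotted by the log2 difference of the arrays labelled as knockout minus those labelled as wild type (x axis), with called members in red and the list median as a black bar. The interferon response list has the highest median, 1.06, and the double-positive stage list lies close to 0 with a median of -0.05.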

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

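The data outside the gene comparison held differences too: of the 16139 probe sets with no single gene name, 106 were called between the labels in a limma fit of all 45037 probe sets, 93 of them higher and 13 lower on the arrays labelled as knockout. The probe set 1456060_PM_at differed most, with 3.64 and 3.34 on the arrays labelled as wild type and 10.6 and 10.4 on those labelled as knockout, and 1437605_PM_at was the lowest, with 6.61 and 7.06 against 2.80 and 2.74. Their genes are unnamed here. In the tests below, the one on swapped genotype labels and the one on the background floor were set before their results were seen, and the others after.

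The higher Gfi1 signal (1.27 on the log2 scale) on the arrays labelled as knockout has 3 candidate explanations. A wrong label on 1 array is argued against, since the lowest correlation between arrays of one label exceeded the highest between labels by 0.00386. A swap of both genotypes stays open: the published targets, genes that Gfi1 is known mostly to repress, had a median difference of 0.0749, above 0, but only Id2 was called, fewer than the 3 the test asked for. A transcript of the recombined allele that keeps the measured 3' part, raised by the loss of a repressor acting on its own gene, was not tested, as the place of the probe set is not known here. Of the 19 measured targets, 17 differences lay above 0 (camera, adjusted p = 0.00589, 0.00857 on ranks and 0.421 with an estimated correlation). Some of these were close to 0, such as Ets1 (0.004) and Meis1 (0.015). Gfi1b (0.03) lay near the lower quartile of all probe sets, where a sign carries little information. The count of signs therefore does not decide on a swap. Since so few targets were called and the list call depends on the assumed correlation, labels as given and swapped labels cannot be told apart with these values.

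Genes of other cell types were higher on the arrays labelled as knockout, and admixed cells that the sort on CD4 and CD8 should have removed are a candidate explanation. For Ctss, myeloid or dendritic cells are argued against: Lyz2, Tyrobp, Fcer1g, H2-Aa, H2-Ab1 and Cd74 had a median difference of 0.0462 (SE over the 6 genes 0.08) and group means of at most 5.60 on the arrays labelled as knockout. For Cd163l1, admixed gamma-delta T or innate lymphoid cells would have to make up 17.2% of the sample. This takes them to be as bright as the brightest probe set on any array (13.5). Double-positive genes absent from such cells would then change by -0.27 on the log2 scale. The mean of Rag1 and Rag2 changed by 0.01 ± 0.04 (SE), which argues against such a share. The median difference of the 26 double-positive genes was -0.05. It does not decide, because the list holds genes such as Cd2 and Cd27 that other T cells can express. Still, 6 of the 26 were lower by that much or more, so gamma-delta T or innate lymphoid cells are not excluded. For Cd53, mature single-positive cells of that brightness would need 29.3% and a change of -0.50, and dimmer cells a larger share and a larger fall. Rag1 and Rag2 did not fall, which argues against such a share. Dntt alone of the 26 reached that change (-0.69). The list also holds Cd4, Cd8a and other genes that mature T cells can express, so members that did not fall decide little. RMA compresses bright signals such as that of Rag1, so mature single-positive cells are not excluded beside a change of expression within double-positive cells.

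Among the 190 called genes 161 were higher. A floor below which dim genes cannot fall is argued against as the whole cause: of the 45 called genes with a mean of at least 8, 41 were higher, 91.1% (exact 95% interval 78.8% to 97.5%), and 0 of these 45 had a group mean under 5. The authors' normalization stays open: median centring or a second quantile normalization left a share of at least 83.1%, but with medians already equal these move almost nothing. The higher share of calls was smaller without either knockout array. Such a fit takes the spread between arrays from the wild-type arrays alone. Whether that spread or the array left out changed the size of the excess was not tested. The loss of a repressor, the difference that the labels name, is consistent with this excess and stays open as untested.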

How the results depend on the processing

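The directions of the 52 genes named by the fixed rule were the same under every alternative run for them (50 of the 52 passed the filters on dim probe sets), except that Hba-a1, not called in any, turned without wild-type replicate 1 or knockout replicate 2. The number of called genes, 190 in the reported fit, lay between 138 and 233 under the alternatives fixed before the data were examined, leaving out arrays and an ordinary t statistic apart, and at 2-fold or more it was 178 against 138 to 219. The ordinary t statistic, with 2 degrees of freedom, called 0 genes after adjustment (1219 at an unadjusted p under 0.05, against 1417 with limma's moderation), so the calls rest on moderation across genes. Leaving out 1 array gave 103 to 475 calls, and 102 to 411 at 2-fold or more, where the lone array is assumed to vary like the other label. All 190 genes were called again without either knockout array, and 98 or 96 of them without wild-type replicate 1 or 2. The higher share of calls fell to 62.5% without knockout replicate 1 and 69.6% without knockout replicate 2. With the mean of the cell cycle list as a covariate, chosen after seeing the data, 502 genes were called (338 higher) and 372 at 2-fold or more. The difference of Gfi1 ranged from 1.19 to 1.35 when 1 array was left out. The labels do not say that replicate numbers pair the arrays. With the replicate block 183 genes were called, 159 of them among the 190, and 171 at 2-fold or more. The deviations of same-numbered arrays from their group means correlated at 0.30 over all probe sets, a hint from the data and not from the design. Of these 52 genes, 10 calls were lost without the intensity trend: Dntt, Fn3k, Id2, Irf4, Jun, Papss2, S1pr1, Tdrd5, Tmie and Usp18. With the mean of all probe sets 5 were lost: Dntt, Irf4, Jun, Papss2 and Tmie. The block lost 6 (S1pr1, Stat4, Jun, Fn3k, Tdrd5 and Tmie) and gained 3 (Car2, Epcam and Pmaip1). Leaving out knockout replicate 1 or 2, with 1 knockout array left, gained calls among the 52 genes and lost none. With an estimated correlation every list call was lost: adjusted p was 0.361 for FOXO1-linked genes and for effector transcription factors, 0.421 for T cell receptor induced genes and for published Gfi1 targets, 0.373 for effector cytokines, 0.319 for the gamma-delta and innate lymphoid and the interferon lists, 0.379 for immediate-early genes and 0.239 for single-positive maturation. With fry the losses were T cell receptor induced genes (0.359), effector transcription factors (0.0974), effector cytokines (0.123), immediate-early genes (0.297) and published Gfi1 targets (0.325). On ranks they were FOXO1-linked genes (0.391) and the gamma-delta and innate lymphoid list (0.0992). Without the dimmest 50% of probe sets the myeloid (0.0213) and thymic epithelial (0.0317) lists were called higher. Leaving out 1 array moved the adjusted p of these lists across 0.05: T cell receptor induced genes 0.00447 to 0.214, T cell receptor signalling 0.0342 to 0.927, cell cycle 7.32e-20 to 0.475 with opposite directions, double-positive stage 0.0120 to 0.869, immediate-early 0.00116 to 0.110, myeloid 0.00116 to 0.824, published Gfi1 targets 0.00116 to 0.110, and thymic epithelial 0.00980 to 0.823. The causes were not tested. With dim probe sets the signal over background is unknown, and genes changed by 1 on the log2 scale were found in under 50% of simulated cases.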

Other observations

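Several called genes outside the fixed lists, chosen after their values were seen, add to the picture. The largest difference of all belonged to 5830411N06Rik, a gene known by a clone name, which rose 430-fold, with 3.03 and 2.98 on the arrays labelled as wild type against 11.75 ± 0.04 (SD, n = 2) on those labelled as knockout (limma, adjusted p = 2.42e-05). Among further single genes, Tnfrsf25 rose 8.73-fold, Lta, which encodes lymphotoxin alpha, 6.26-fold and Tnfsf11, which encodes RANKL, 4.87-fold, with the adaptor gene Traf5 9.17-fold. Il6ra, the interleukin-6 receptor chain, rose 18.2-fold, Gpr183, an oxysterol receptor, 21.4-fold, Cd7 15.8-fold and Btla, an inhibitory receptor, 4.46-fold. Iigp1 rose 9.88-fold, Tgtp1 7.10-fold, Oas1g 5.82-fold, Sting1, the adaptor of cytosolic DNA sensing, 3.70-fold and Ddx60 3.70-fold. Among the decreases, Itga4, the integrin alpha 4 chain, fell 3.23-fold, Ldhb, a lactate dehydrogenase gene, 2.93-fold from 11.90 ± 0.02 to 10.34 ± 0.58 (SD, n = 2 each), and Eya2 2.98-fold. All of these passed an adjusted p of 0.05 in limma, and no gene group was tested here.

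The test over the whole chromosome below was set before its result was seen, the others after. One hypothesis was that genes linked to the floxed allele differ because they may carry sequence of another strain. Of 1049 genes tested on the chromosome of Gfi1, 13 were called (1.24%), against 176 of 15886 elsewhere (1.11%; odds ratio 1.12, 95% interval 0.583 to 1.97; Fisher's exact test, two-sided, p = 0.649), which argues against a chromosome-wide excess of 2-fold or more. Within 20 Mb of Gfi1 5 of 380 genes were called (odds ratio 1.19, 95% interval 0.378 to 2.84; Fisher's exact test, p = 0.619), which leaves a local effect open.

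A further hypothesis was that raised genes lie next to each other on chromosomes more often than chance, as Cd163l1 and 5830411N06Rik do. Among 16936 genes in chromosome order, 4 adjacent pairs were both called higher: Cd163l1 with 5830411N06Rik, Pdlim4 with P4ha2, Mllt6 with Cisd3, and Ahcyl2 with Strip2. Random draws of 161 genes gave 1.52 such pairs on average (permutation test with 100000 draws, one-sided p = 0.0662), so the excess did not pass 0.05 and chance was not excluded. The pair named in the hypothesis is itself among the 4, which favours a low p.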
